A study of Mus musculus with 8 samples.

How the data were processed

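RNA was sequenced from fibroadipogenic progenitors of 8 mice: 2 with sham surgery, 3 with KPCY cells carrying a scrambled sequence in the pancreas and 3 with KPCY cells in which a lentiviral vector inhibited miR-27a-3p. Per the labels, the transduced cells were selected for 7 days with 2 µg/mL of puromycin, and cells in a volume of 50 µL were injected. Cells without CD31, CD45, α7-integrin or propidium iodide, and with SCA-1 and Hoechst, were sorted. RNA with an integrity number of at least 7 went into Illumina stranded mRNA libraries, which were sequenced on a NextSeq 2000 as paired reads of 59 bases. The labels give no collection times, sorting days or library batches.

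The authors deposited a table of raw counts, whole numbers of reads per gene symbol, with 1 column for each of the 8 libraries and 24419 rows. Per the submitters' processing notes the genome build was mm10, and the tools were bcl2fastq 2.20, Bowtie, STAR, DESeq2 1.36.0 and R 4.2.1, without their roles. The counting tool, the annotation and the counting strand are not given in the sources used here. There, 25 gene symbols had been turned into dates, 6786 rows held 0 in every library, and 98.4% of symbols matched GENCODE M21, from which gene identifiers and coordinates (GRCm38, the same build as mm10) were taken. Total counts ran from 15647436 to 28340450 per library. Gsn took between 5.00% and 6.74% of the counts of a library, the most of any gene. Counting error covers reads and not molecules, since the libraries had no molecular identifiers.

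The libraries were compared in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr (a minimum count of 10 and a total of 15) and scaled by TMM, and 13646 genes remained. The quasi-likelihood fit (robust, not the legacy method) used 3 group means over all 8 libraries, so that the groups share a dispersion. Tests were two-sided and adjusted by Benjamini and Hochberg over all genes tested, with a threshold of 0.05. Errors of CPM are SDs and errors of log2 fold changes are standard errors. The latter were derived from the test, as the absolute log2 change divided by the square root of its F statistic. The comparisons were scrambled against sham, knockdown against scrambled and knockdown against sham, with the overlap and correlation of their changes. For the shared groups, 50 data sets were drawn from negative binomial distributions with no effect, and 50 with the knockdown and scrambled means both set to the mean of their 6 libraries. Groups were called apart when their log2 CPM did not overlap. Replicate numbers were not used as a block in the reported fit.

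The genes to be named were set by a rule before the data were examined, as were the lists and alternatives. For each comparison these were, among called genes with a mean CPM of at least 5, a gene name that is not a clone or prediction and groups that did not overlap, the 10 with the largest rise and the 10 with the largest fall. If none passed in a direction, the 3 with the smallest p were taken. Up to 4 members of each list with the smallest p, the gate genes, Xist and Ddx3y, the precursor gene Mir27a and up to 10 genes called in both directions were added; only part of these are printed, and some single-gene results are not reported here. Xist reads were near 0 and Ddx3y was present in each library, as the labels of male mice imply.

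The gene lists covered progenitor identity, the Dpp4 Pi16 and Cxcl14 Col15a1 subsets, collagens, other matrix, matrix proteases, TGF-beta response, adipogenesis and lipid handling, acute phase and IL-6/STAT3, chemokines, NF-kappa-B targets, interferon response, MHC class I, complement, glucocorticoid and fasting response, secreted factors acting on muscle, reported miR-27a targets, cell cycle, p53 and senescence, unfolded protein response, glycolysis and hypoxia, oxidative phosphorylation, cytosolic ribosomal proteins, mitochondrially encoded transcripts, immediate early genes and the circadian clock. The lists of other cell types covered macrophages, neutrophils, lymphocytes, endothelium, muscle stem cells, muscle fibres, tenocytes, pericytes, Schwann cells, mature adipocytes, red blood cells and epithelial tumour cells. The list of immediate early genes also holds genes of dissociation stress. The lists come from general knowledge, and some genes stand in more than 1 list. Lists with at least 5 tested members were tested with camera of limma 3.58.1 on log2 CPM (prior count 2, preset correlation 0.01), adjusted over the lists of each kind within a comparison. Beside it stand camera with an estimated correlation, fry, and counts of members adjusted over the list alone.

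The fit was tested on simulated data made from the mean and dispersion of these counts, with 50 genes changed by each fold. For scrambled against sham it recovered 18%, 62%, 84% and 94% of genes changed by 2, 4, 8 and 16 fold, with 9 false calls among 13413 genes. For knockdown against scrambled it recovered 30%, 76%, 86% and 92%, with 6 false calls, and for knockdown against sham 20%, 72%, 90% and 94%, with 7. A shifted complement list ranked first of 35 lists and no other list was called. Alternatives, each changing 1 choice, were RLE, upper-quartile or no composition factors, no low-count filter or a stricter one (10 reads in 3 libraries and a mean CPM of 1), DESeq2 1.42.0, limma-voom, edgeR's legacy and non-robust fits, a log2 fold threshold of 1, a threshold of 0.1, a fit of the compared groups alone, a block for the replicate number, and leaving out each of the 8 libraries. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9. No library was left out of the reported values.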

Results

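Gene expression was measured by RNA sequencing in fibroadipogenic progenitors, the stromal cells of skeletal muscle that can give rise to fibroblasts and adipocytes. The cells were sorted from the hindlimb muscle of male C57BL/6J mice as SCA-1 positive cells without CD31, CD45 or α7-integrin. There were 8 libraries in 3 groups. In the sham group (n = 2) the mice had sham treatment. In the scrambled group (n = 3) the mice carried orthotopic tumours of KPCY cells, a mouse pancreatic cancer line, transduced with a scrambled sequence. In the knockdown group (n = 3) the KPCY cells carried a lentiviral inhibitor of miR-27a-3p. The inhibitor was in the implanted cells, not in the sorted progenitors. Total counts were 15647436 and 17384878 in sham libraries 1 and 2, 28340450, 23801522 and 16183771 in scrambled libraries 1, 2 and 3, and 18929965, 17454630 and 22197054 in knockdown libraries 1, 2 and 3. After a filter on low counts, 13646 genes were tested. The labels call the libraries biological replicates. The p-values rest on a spread between mice pooled over all 3 groups, so each also draws on the group not compared.

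Pdgfra, the receptor that marks these progenitors, stood at 1422 ± 235 normalised CPM (counts scaled by library size and TMM factor; mean ± SD, n = 2) in sham, 1560 ± 36.2 (n = 3) in scrambled and 1464 ± 13.8 (n = 3) in knockdown libraries. Ly6a, which encodes SCA-1, stood at 942 ± 12.9, 674 ± 400 and 1106 ± 71.5 CPM in the same order. Neither was called between any pair of groups (edgeR, adjusted p from 0.184 to 1). Ly6a was uneven, at 451, 1136 and 436 CPM in scrambled libraries 1, 2 and 3 against 951 and 933 in sham. Without scrambled library 2 its log2 change was -1.08 from sham to scrambled (edgeR, adjusted p = 0.000119, up to 0.718 over its alternatives) and 1.31 from scrambled to knockdown libraries (1.69e-05, up to 0.433). Transcripts of the proteins gated against were low: the mean of Pecam1 (CD31) ran from 25.0 to 55.6 CPM over the groups, that of Itga7 from 3.40 to 8.61 CPM and that of Ptprc (CD45) from 0.218 to 1.28 CPM, and none was called between groups (adjusted p from 0.0802 to 1). Pecam1 and Itga7 were called higher in scrambled than in sham libraries with DESeq2 (log2 1.17 and 1.35) and without scrambled library 2 (1.39 and 1.29), with an adjusted p over their alternatives from 0.00039 to 0.397 and from 0.023 to 0.438. Without that library Pecam1 was also called lower in knockdown than in scrambled libraries (-0.58; from 0.0231 to 0.817). The first principal component of log2 CPM held 61.1% of the variance. Scrambled libraries 1 and 3 lay at 115 and 92.0 on it and scrambled library 2 at -12.3. The 5 sham and knockdown libraries lay between -47.7 and -32.3, so the libraries of the scrambled group were spread more widely than those of the other groups. The gene for the miR-27a precursor had 12, 12 and 3 reads in the scrambled libraries and 0 in each sham and knockdown library, too few to be tested. A count of 0 allows up to 3 reads by counting error alone, and libraries of polyadenylated RNA do not measure mature microRNA.

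The comparison of scrambled with sham libraries asked how these progenitors differ in mice with a pancreatic tumour, in a series titled for pancreatic cancer cachexia. Several genes of secreted proteins rose steeply. Serpina3n, a secreted serine protease inhibitor, stood at 1645 ± 422 CPM (SD, n = 3) against 76.3 ± 0.152 (n = 2), 21.6-fold higher (log2 4.43 ± 0.31 SE). C4b, the complement component, rose 13.2-fold, from 302 ± 31.3 to 3984 ± 440 CPM (log2 3.72 ± 0.24), and Agt, the precursor of angiotensin, rose 21.1-fold, from 4.17 ± 1.60 to 88.5 ± 12.5 CPM (log2 4.40 ± 0.30). Cxcl13, a chemokine that attracts B cells, rose 31.5-fold, from 14.5 ± 4.08 to 457 ± 205 CPM (log2 4.98 ± 0.46). Pthlh, which encodes parathyroid hormone-related protein, fell by 3.56 ± 0.42 on the log2 scale, from 39.3 ± 10.2 to 3.19 ± 1.84 CPM. By edgeR's quasi-likelihood test 150 genes were higher and 65 lower, and the smallest adjusted p, 0.000801, belonged to Serpina3n, C4b and Agt.

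The other genes with the largest rises were Hp (log2 5.97 ± 0.99), which encodes the haemoglobin-binding protein haptoglobin, Tmod1 (5.68 ± 1.05), Serpina3m (5.01 ± 0.43), Aspg (4.79 ± 0.89), Pdk4 (4.78 ± 0.95), a kinase that restrains glucose oxidation, Lcn2 (4.52 ± 0.64), the iron-trapping lipocalin, and Slc4a8 (4.49 ± 0.70). Some of these rises were uneven: in scrambled libraries 1, 2 and 3 Hp stood at 29.3, 22.7 and 4.35 CPM, Pdk4 at 520, 48.0 and 642, Tmod1 at 14.2, 3.04 and 20.7 and Aspg at 20.5, 6.17 and 38.6. Without scrambled library 3 the log2 change of Aspg was 4.10. The other largest falls were those of Prrt4 (-4.58 ± 0.65), Gap43 (-3.71 ± 0.72), which encodes a growth-cone protein of axons, Fgf1 (-3.46 ± 0.58), Sqle (-3.42 ± 0.52) and Hmgcs1 (-2.55 ± 0.50), which encode enzymes of cholesterol synthesis, Necab3 (-3.10 ± 0.59), Igdcc4 (-3.01 ± 0.57), Dact2 (-2.98 ± 0.54) and Efcc1 (-2.33 ± 0.47). Of these, Prrt4, Gap43, Fgf1, Necab3, Igdcc4, Dact2 and Efcc1 were highest in scrambled library 2, with Gap43 at 0.196, 2.79 and 0.063 CPM and Prrt4 at 0.0784, 1.90 and 0.126 CPM in scrambled libraries 1, 2 and 3. Without scrambled library 2 their log2 changes were, in the order named, -7.44, -6.56, -4.66, -4.12, -4.11, -3.95 and -3.21. Sqle and Hmgcs1 were also highest in scrambled library 2. In scrambled libraries 1, 2 and 3 Sqle stood at 2.47, 2.49 and 2.43 log2 CPM and Hmgcs1 at 4.56, 4.85 and 3.76. Serpina3n lies on chromosome 12 from 104406729 to 104414329 and Serpina3m from 104338486 to 104394257 (mm10, both on the + strand). C4b lies on chromosome 17 from 34728380 to 34743882 and Agt on chromosome 8 from 124556534 to 124569706 (both on the - strand). Reads of Serpina3m and Serpina3n, and of C4b and its near copy C4a, can be shared between the copies, so the split between them is uncertain.

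**Figure D1:**
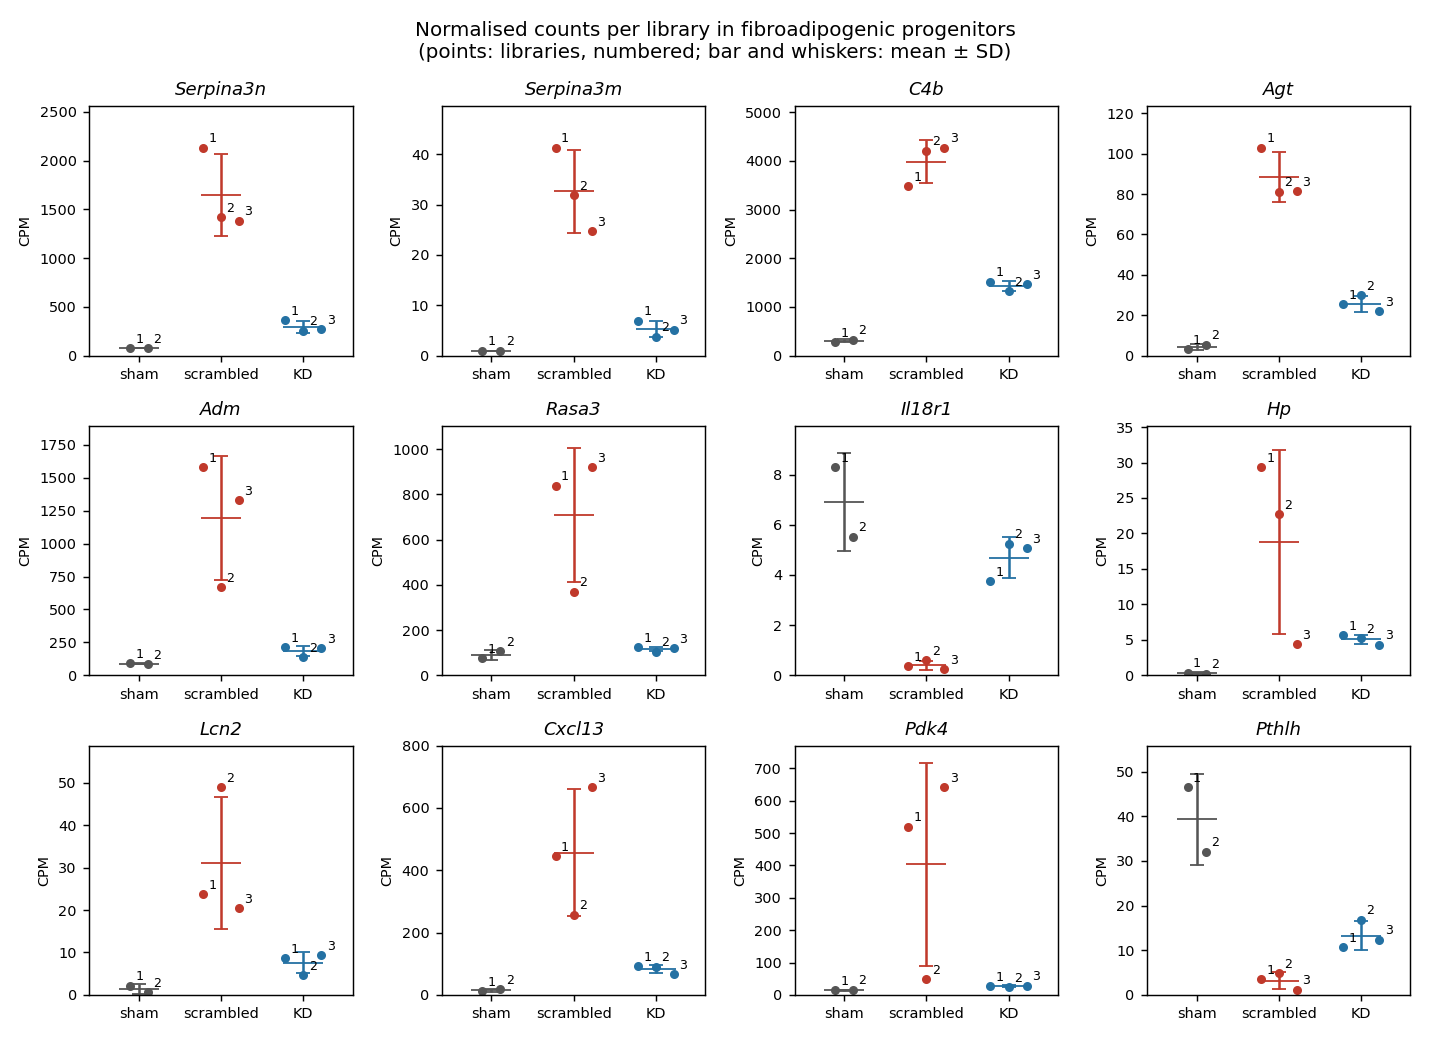
Normalised counts (CPM, linear axis from 0) of 12 genes in each library, with the group on the horizontal axis. Points are libraries with their replicate number, and the bar and whiskers are the mean and SD (n = 2 sham, 3 scrambled, 3 knockdown); for C4b the 3 knockdown libraries lie between the sham and the scrambled libraries, at a mean of 1433 CPM.

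Of 25 gene lists fixed beforehand, 14 passed camera with its preset correlation (adjusted p from 5.61e-12 to 0.0435), and none passed with a correlation estimated from the data (adjusted p from 0.161 to 0.6 for those 14). With camera, the rises and falls of lists in this paragraph therefore rest on the preset correlation. Fry, which tests a list without comparing it with other genes, called 10 of those 14 (adjusted p from 0.00206 to 0.0495). By fry the other matrix, progenitor identity, circadian clock and interferon response lists were not called (adjusted p from 0.135 to 0.298). The glucocorticoid and fasting response list rose as a set (adjusted p from 9.21e-14 to 0.471 over 12 alternatives, the highest with an estimated correlation): 20 of its 20 tested members were higher when adjusted over the list alone and 5 over all genes, among them Angptl4 (log2 4.14 ± 0.65), an inhibitor of lipoprotein lipase, Gadd45g (1.73 ± 0.24) and Klf9 (2.04 ± 0.38). In the acute phase and IL-6/STAT3 list 17 of 20 members were higher and 1 lower when adjusted over the list alone, and 9 were higher over all genes, among them Osmr (2.00 ± 0.22), the oncostatin M receptor, Pim1 (3.13 ± 0.45) and Cebpd (2.06 ± 0.32). The list of the Dpp4 Pi16 subset, markers of an early progenitor state, fell: 12 of 16 members were lower when adjusted over the list alone and 3 over all genes, Limch1 (-1.34 ± 0.20), Dact2 and Fbn1 (-2.31 ± 0.46). Collagens fell, with 9 of 18 lower when adjusted over the list alone and 1 over all genes, Col18a1 (-1.90 ± 0.35); other matrix genes also fell as a set (3 of 30 higher and 7 lower when adjusted over the list alone), although Lox (3.72 ± 0.54), which crosslinks collagen, and Thbs2 (2.17 ± 0.42) rose. Adipogenesis and lipid genes rose, with 14 of 20 higher and 2 lower when adjusted over the list alone and 3 higher over all genes, Cd36 (2.11 ± 0.32), Cebpb (2.23 ± 0.42) and Cebpa (0.90 ± 0.18). The mature adipocyte list, which shares Adipoq, Plin1, Cidec and Pck1 with this list, was higher too, with 7 of 7 members positive (camera, adjusted p = 0.00983, from 0.000949 to 0.517 over its alternatives). Cytosolic ribosomal protein genes rose, with 16 of 25 higher when adjusted over the list alone and 0 over all genes, where 25 of 25 had a positive log2 change. Reported targets of miR-27a, chosen from general knowledge, were higher as a set, with 8 of 25 higher when adjusted over the list alone and 2 over all genes, Cyp1b1 (3.09 ± 0.39) and Runx1 (1.97 ± 0.28). Complement was higher (4 of 13 higher and 1 lower over the list alone, 3 higher over all genes), as were matrix proteases and their inhibitors (6 of 22; 2 over all genes, Ctsk and Mmp11), immediate early and dissociation stress genes (13 of 25 higher and 1 lower; 2 over all genes) and the circadian clock list (6 of 18; 3 over all genes, Nfil3, Per2 and Cry1). Interferon response genes (0 of 24 passing alone) and the progenitor identity list (4 of 18 lower alone, 0 over all genes) were lower as sets.

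Over the same 12 alternatives the adjusted p of the acute phase list ran from 5.08e-15 to 0.161 and that of the collagens from 8.01e-08 to 0.471 by camera or fry. Some calls rested on single libraries. The complement list was not called without scrambled library 2 (limma camera, adjusted p = 0.231, from 1.99e-05 to 0.471 over its alternatives) or the protease list without sham library 2 (0.0612, from 0.00265 to 0.366). The interferon list was not called without scrambled library 1, the clock list without scrambled library 1 or 3, and the progenitor identity list without sham library 2, scrambled library 1 or 3 or knockdown library 2 (camera adjusted p up to 0.191, 0.0853 and 0.0837, with alternatives from 0.00231 to 0.6). The lists of the Cxcl14 Col15a1 subset, TGF-beta response, chemokines, NF-kappa-B targets, MHC class I, secreted factors acting on muscle, cell cycle, p53 and senescence, unfolded protein response, glycolysis and hypoxia, and oxidative phosphorylation did not pass (adjusted p from 0.111 to 0.981). Single members of these passed over all genes, among them Ctgf (2.67 ± 0.40), Gas6 (1.94 ± 0.25), Igfbp5 (-2.22 ± 0.35) and Inhba (-2.24 ± 0.44). The secreted factor list had a median log2 change of -0.13 and a mean of 0.18, the glycolysis list -0.25 and 0.23, and the cell cycle list 0.23 and -0.16. The table held no mitochondrially encoded genes.

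Of the lists of other cell types, muscle fibre (median log2 change 1.10), mature adipocyte (4.19) and neutrophil genes (1.55) were higher in scrambled than in sham libraries (adjusted p = 0.00983, 0.00983 and 0.0492), and none passed with an estimated correlation (adjusted p = 0.634, 0.517 and 0.517, the highest over the 12 alternatives of each; the lowest were 3.53e-05, 0.000949 and 0.00163). Muscle fibre genes were 0.34, 0.70 and 2.31 log2 CPM above the sham mean in scrambled libraries 1, 2 and 3, and they summed to at most 368 CPM. Mature adipocyte genes summed to at most 56.7 CPM, and were 2.93, 1.77 and 3.20 log2 CPM above the sham mean. The muscle fibre call was lost without sham library 1 (limma camera, adjusted p = 0.0522), and the neutrophil call without sham library 2 or scrambled library 2 (adjusted p up to 0.234). Macrophage, endothelial, muscle stem cell, tenocyte, pericyte, Schwann cell and epithelial lists did not pass (adjusted p from 0.107 to 0.876). The tenocyte list, none of whose members is in the collagen list, had the lowest of these and went in the direction of the collagens. It had a median log2 change of -1.29, 8 of 10 members negative and 3 lower when adjusted over the list alone. No lymphocyte gene passed the filter on counts. The red blood cell list had 2 tested members, too few for a test, with a median log2 change of 5.90.

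In this comparison 3990 genes had an unadjusted p under 0.05, and the groups did not overlap for 5600 genes, 41% against 20% by chance. The count of called genes depended on single libraries: it was 0 without sham library 1 (1711 genes at an unadjusted p under 0.05), 2 higher and 0 lower without sham library 2, 57 and 10 without scrambled library 1, 3441 and 3467 without scrambled library 2, and 45 and 4 without scrambled library 3. It was 12 and 2 without knockdown library 1 and again without knockdown library 2, and 7 and 0 without knockdown library 3. DESeq2 called 1321 genes higher and 753 lower, limma-voom 100 and 51, and edgeR's legacy method 106 and 27. A fit of these groups alone called 4 genes higher and 0 lower (2280 at an unadjusted p under 0.05).

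**Figure D2:**
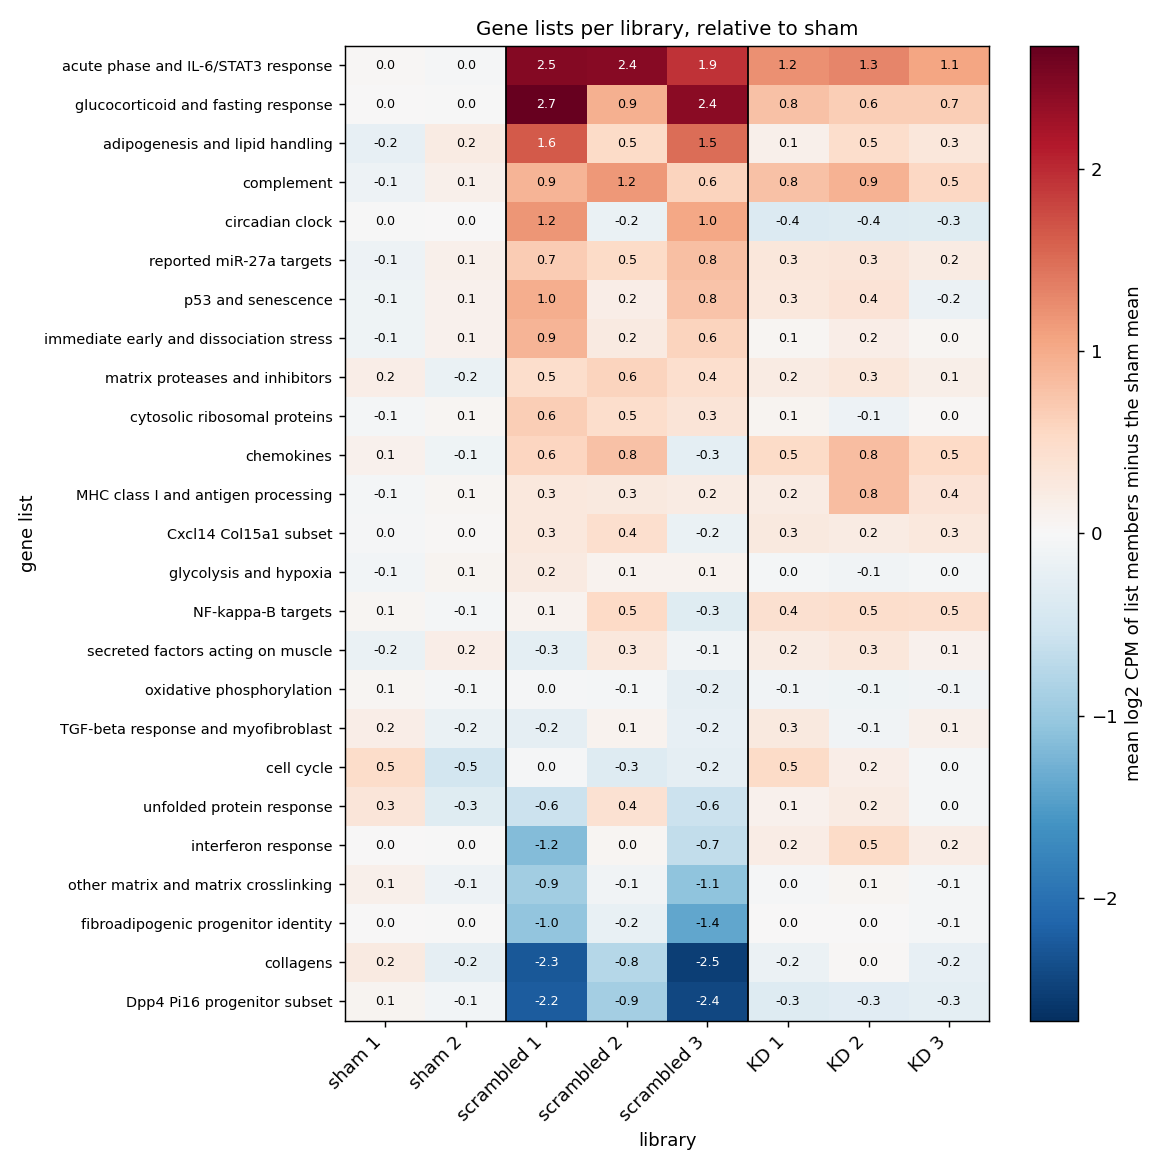
Mean log2 CPM of the tested members of 25 gene lists in each of the 8 libraries, minus the mean of the 2 sham libraries. Rows are lists in the order of their mean in the scrambled group, and colour and printed values give the difference in log2 CPM; the glucocorticoid, collagen and Dpp4 Pi16 lists are nearer to sham in scrambled library 2 than in scrambled libraries 1 and 3.

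The comparison of knockdown with scrambled libraries asked whether the progenitors differ when miR-27a-3p is inhibited in the tumour cells. Serpina3n, C4b and Agt, which were higher in scrambled than in sham libraries, were lower in knockdown than in scrambled libraries. Serpina3n fell by 2.47 ± 0.24 on the log2 scale, to 296 ± 59.9 CPM (SD, n = 3) from 1645 ± 422 (n = 3), and C4b fell by 1.47 ± 0.19, to 1433 ± 101 from 3984 ± 440 CPM. Serpina3m (-2.62 ± 0.29), Agt (-1.79 ± 0.21), Adm (-2.69 ± 0.33), which encodes the vasodilator adrenomedullin, and Rasa3 (-2.61 ± 0.33), an inhibitor of Ras and Rap signalling, fell too. Il18r1, a subunit of the interleukin-18 receptor, rose 11.2-fold, from 0.399 ± 0.175 to 4.69 ± 0.821 CPM (log2 3.49 ± 0.45). These 7 genes, 1 higher and 6 lower, were those that edgeR called (adjusted p from 0.0357 to 0.0491).

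Of the 25 gene lists, 12 passed camera with its preset correlation (adjusted p from 8.01e-10 to 0.0154), and kept the call when any single library was left out. None held with an estimated correlation (adjusted p = 0.504 for each of the 12, the highest over their alternatives, which began between 1.11e-14 and 0.00578). Leaving out 1 library at a time cannot show whether scrambled libraries 1 and 3 carry a call together. Clock output genes (Dbp, Nr1d1, Nr1d2, Per3, Tef and Hlf) lay on average at -1.06 log2 CPM from the sham mean in scrambled library 2, although Hlf lay above both sham libraries there. They lay at 0.50 and 0.70 in scrambled libraries 1 and 3, and from -1.29 to -0.86 in the knockdown libraries. The acute phase list in scrambled library 2 lay above the knockdown libraries, at 6.82 against at most 5.69 log2 CPM. By the preset correlation, ribosomal protein genes fell as a set (22 of 25 lower when adjusted over the list alone, 0 over all genes), as did the glucocorticoid and fasting list (17 of 20 lower alone, 0 over all genes; Pdk4 at -3.93 ± 0.76) and the circadian clock list (2 higher and 14 lower of 18 alone, 0 over all genes; Per2 at -1.92 ± 0.30). The acute phase list fell (1 higher and 12 lower of 20 alone, 1 lower over all genes), as did adipogenesis and lipid genes (1 higher and 12 lower of 20 alone), immediate early and dissociation stress genes (8 of 25 lower alone) and the reported miR-27a targets (7 of 25 lower alone, with Runx1 at -1.15 ± 0.23). In those last 3 lists 0 members passed over all genes. The Dpp4 Pi16 list (11 of 16 higher alone; Wnt2 at 2.13 ± 0.45), collagens (10 of 18 higher alone; Col6a2 at 2.19 ± 0.60), other matrix genes (5 higher and 3 lower of 30 alone), interferon response genes (1 of 24 higher alone, Ifit1 at 1.37 ± 0.32) and the progenitor identity list (0 of 18 passing alone) were higher as sets, with 0 members over all genes. The other 13 lists did not pass (adjusted p from 0.103 to 0.996). The glycolysis list had a median log2 change of 0.14 and a mean of -0.30, the epithelial list -0.64 and 0.04, and the pericyte list -0.07 and 0.01, a median whose sign changed with the scaling. Among other cell types muscle fibre genes were lower (4 of 15 alone; median log2 change -1.35) and tenocyte genes higher (3 of 10 alone; 1.19), each with 0 over all genes and a limma camera adjusted p = 0.0325. Both calls were lost with an estimated correlation (adjusted p = 0.996, the highest over the alternatives; the lowest were 9.22e-05 and 0.00448) and without scrambled library 2, scrambled library 3 or knockdown library 1 (adjusted p up to 0.356). The other 8 cell type lists tested did not pass (adjusted p from 0.102 to 0.996). The mature adipocyte list had the lowest of these and went in the direction of the adipogenesis list, with which it shares 4 members. It had a median log2 change of -1.40, 7 of 7 members negative and 2 lower when adjusted over the list alone. The 2 red blood cell genes, too few for a test, had a median of -3.90, and both were lower over the list alone.

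At an unadjusted p under 0.05 there were 4428 genes, and the groups did not overlap for 34.2% of genes, against 10% by chance. All 7 called genes were apart in every library of the 2 groups. DESeq2 called 792 genes higher and 1528 lower, limma-voom 0 and 5, edgeR's legacy method 0 and 1, and a fit of these groups alone 0 and 0 (3622 at an unadjusted p under 0.05). Without scrambled library 2 the fit called 3705 higher and 3608 lower, without scrambled library 1 it called 0 and 1, and without scrambled library 3 it called 0 and 4. It called 0 without either sham library or any knockdown library, with 2713 to 3798 genes at an unadjusted p under 0.05. Without composition factors the median log2 change of all genes moved by 0.10, more than in any other comparison or scaling, and 0 genes were called higher and 1 lower.

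The comparison of knockdown with sham libraries asked what remained of the difference from sham when miR-27a-3p was inhibited in the tumour. C4b rose 4.74-fold (log2 2.25 ± 0.22), from 302 ± 31.3 (n = 2) to 1433 ± 101 CPM (n = 3), and was the 1 gene called by edgeR (adjusted p = 0.0445). Agt had a log2 change of 2.61 ± 0.29 (edgeR, adjusted p = 0.051), Serpina3n 1.96 ± 0.28 (0.25) and Cxcl13 2.52 ± 0.41 (0.539). No gene was called lower. The genes with the smallest p on that side, Dbp (-2.58 ± 0.59), a clock-controlled transcription factor, Pgf (-0.95 ± 0.23), the placental growth factor, and Tnfrsf21 (-0.80 ± 0.19), had an adjusted p of 1.

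The acute phase list was higher as a set, with 6 of 20 members higher when adjusted over the list alone and 0 over all genes, among them Serpina3n, Il6 (log2 2.05 ± 0.50) and Osmr (0.75 ± 0.21). This was the 1 list whose call held with an estimated correlation (adjusted p = 0.0344) and under each of the 12 alternatives (adjusted p from 4.23e-24 to 0.0351). The complement list was higher (2 of 13 alone, C4b and C2; adjusted p = 1.25e-09, and 0.213 with an estimated correlation, the highest of its alternatives, from 5.28e-12), as were chemokines (1 of 14 alone, Cxcl13) and reported miR-27a targets (1 of 25 alone, Cyp1b1). The glucocorticoid and fasting, MHC class I, interferon, NF-kappa-B, adipogenesis, Cxcl14 Col15a1, secreted factor and matrix protease lists were higher as sets with 0 members passing alone, and the Dpp4 Pi16 and oxidative phosphorylation lists were lower with 0 passing alone. These 14 of 25 lists passed camera (adjusted p from 6.17e-22 to 0.0253). With an estimated correlation the other 13 had an adjusted p from 0.213 to 0.498, and with fry, which tests a list without comparing it with other genes, up to 0.767. Without sham library 1 the adipogenesis, Cxcl14 Col15a1, oxidative phosphorylation, miR-27a target and secreted factor lists were not called (adjusted p from 0.0604 to 0.412). Without sham library 2 the protease list was not called (0.322), and without knockdown library 2 the adipogenesis, protease and secreted factor lists were not called (up to 0.09). Over their alternatives the adjusted p of these 6 lists ran from 0.000581 to 0.697. The other 11 lists did not pass (adjusted p from 0.0898 to 0.891), among them the circadian clock list, where Nfil3 (1.57 ± 0.33) was higher and Dbp and Bhlhe41 (-1.31 ± 0.34) lower when adjusted over the list alone. The progenitor identity list had a median log2 change of -0.01, whose sign changed with the scaling, and the p53 list had a median of -0.03 and a mean of 0.19.

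Among other cell types, pericyte (2 of 10 alone, Rgs5 and Mcam), Schwann cell (1 of 9 alone), macrophage, mature adipocyte, neutrophil (1 of 6 alone, Il1r2), muscle stem cell and endothelial lists were higher in knockdown than in sham libraries, with camera adjusted p from 6.11e-06 to 0.0331. None held with an estimated correlation (adjusted p from 0.0929 to 0.577), and fry called only the Schwann cell list (adjusted p = 0.0407). Macrophage genes were 1.76, -0.43 and 1.11 log2 CPM from the sham mean in knockdown libraries 1, 2 and 3, and the call was lost without knockdown library 1 (limma camera, adjusted p = 0.263, with alternatives from 2.12e-16 to 0.412). The adipocyte and muscle stem cell calls were lost without sham library 1, the endothelial call without sham library 2 or knockdown library 3, and the neutrophil call without sham library 2, scrambled library 2 or knockdown library 1 (adjusted p up to 0.943, with alternatives from 3.02e-05). The neutrophil list had a median log2 change of 1.30 and a mean of 0.07, with 4 of 6 members positive. Its mean log2 CPM was 0.66 above sham, and -0.23 from it without sham library 2. Muscle fibre, tenocyte and epithelial lists did not pass (limma camera, adjusted p = 0.212, 0.282 and 0.734).

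In this comparison 323 genes had an unadjusted p under 0.05, fewer than the 682 expected by chance, and the groups did not overlap for 27.3% of genes, against 20% by chance. DESeq2 called 24 genes higher and 1 lower, limma-voom and edgeR's legacy method 1 and 0 each, and a fit of these groups alone, which leaves out the spread between the scrambled libraries, 73 and 28. Without scrambled library 2 the fit called 23 and 9. It called 0 without any other library, with 155 to 444 genes at an unadjusted p under 0.05.

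Of the 215 genes called between scrambled and sham libraries, 7 were also called between knockdown and scrambled libraries with the opposite sign: Serpina3n, Serpina3m, C4b, Agt, Adm, Rasa3 and Il18r1. Independent calls would give 0.066 genes for those higher in scrambled and 0.0048 for those lower. Because both comparisons share the scrambled libraries, 50 simulated data sets were drawn with the means of the knockdown and scrambled groups made equal: they gave 0.06 such genes on average and at most 1. Only C4b was called in both tumour groups against sham with the same sign, where 232 genes (173 to 272) were shared in those simulated sets. Those sets gave each gene 1 dispersion in every group, without the wider spread of the real scrambled libraries. They called 399 genes on average between knockdown and sham. The real fit called 1 there, and a fit of those groups alone called 73 higher and 28 lower. The simulated counts are therefore no like-for-like standard for the 7 and the 1. Across all genes tested, the log2 changes of scrambled against sham and knockdown against sham had Pearson's r = 0.58 and Spearman's rho = 0.39 (covariance 0.50), against r = 0.63, rho = 0.57 and a covariance of 0.21 in sets simulated with no effect. Sets with the 2 tumour groups made equal gave r = 0.89, rho = 0.81 and a covariance of 0.97. The changes of scrambled against sham and knockdown against scrambled had r = -0.80 and rho = -0.88 (covariance -0.91), against r = -0.43, rho = -0.41 and a covariance of -0.12 with no effect. With equal tumour groups r was -0.24, rho -0.26 and the covariance -0.12. Genes are not independent replicates, and the simulated sets treat them as independent, so no p-value is given. The simulated sets are no like-for-like standard for these correlations and covariances either. They lack the wider spread of the real scrambled libraries, which enter both changes in the second pair. The count of 7 was 6218 without scrambled library 2, 1 without scrambled library 1, 4 without scrambled library 3 and 0 without any sham or knockdown library. Without scrambled library 2 the count of genes called in both tumour groups against sham was 26, and without any other library it was 0.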

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

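In this part the tests on scrambled library 2 were chosen only after the results were seen, and the count over other splits was planned. For 7 genes the change from sham differed between the tumour groups by a test of the difference itself, the comparison of knockdown with scrambled libraries: Serpina3n, Serpina3m, C4b, Agt, Adm and Rasa3 were lower and Il18r1 higher in the knockdown libraries. The 6 tumour libraries can be split into groups of 3 in 10 ways, too few for a share under 0.05; 1 of the 10, the real split, gave as many genes, with 7 called, and the highest of the others gave 0.

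Scrambled library 2 stood apart from scrambled libraries 1 and 3, at -12.3 against 115 and 92.0 on the first principal component, and leaving it out raised the genes called against sham from 215 to 6908. GC content and transcript length explained at most 1.63% of the variance across genes of a scrambled library's deviation from its group, which argues against such a bias. A sham library under the scrambled label is argued against by the acute phase list. Its mean in this library was 6.82 log2 CPM, against at most 4.40 in sham, and 19 of 20 members lay above both sham libraries. That mean also lay 1.13 above the highest knockdown library, with 15 of 20 members above all 3 knockdown libraries. A knockdown library under the scrambled label stays open, since this rests on 1 list. Across all genes tested, the library was closer to knockdown libraries 1 and 3 (Spearman's rho 0.987 with each) than to scrambled libraries 1 and 3 (0.921 and 0.94). A smaller degree of the whole response is argued against by the acute phase list, whose shift from sham in this library (2.44 log2 CPM) was 1.11 times the mean shift of scrambled libraries 1 and 3. The clock output genes lay on average at -1.06 log2 CPM from sham in this library, against 0.50 and 0.70 in scrambled libraries 1 and 3. They cannot decide the question, since the collection times are not given. For the other genes a smaller degree stays open. With genes called without this library and 1 sham library, and shifts measured from that sham library so that no sham error was shared, 73.4% of 4997 and 69.1% of 5227 genes shifted in the same direction, between the bounds of 60% and 75% set for that test. The knockdown libraries shared the direction of 52.2% to 63.4%. As a share of the log2 change by which the genes were selected, the median shift was 0.18 and 0.13 in scrambled library 2. In the knockdown libraries it ran from 0.012 to 0.080. A difference in tumour burden, stage or collection between the mice stays open and untested, since the labels give none of these.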

How the results depend on the processing

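All alternatives were set with the analysis plan, and where a value moved the cause was not tested unless stated. Between scrambled and sham, 150 genes were higher and 65 lower; the counts were 1321 and 753 with DESeq2, 838 and 578 at an adjusted p under 0.1 (a looser threshold by construction), 4 and 0 in a fit of the groups compared alone, and 27 lower with edgeR's legacy method. Between knockdown and scrambled, 1 was higher and 6 lower. The counts were 0 and 1 with upper-quartile factors, without composition factors, with the strict filter and with the legacy method. They were 792 and 1528 with DESeq2, 825 and 1540 at 0.1, and 0 and 0 in a fit of the groups alone; limma-voom gave 0 higher and no low-count filter gave 10 lower. Between knockdown and sham, 1 was higher and 0 lower. The count higher was 2 with upper-quartile factors, without composition factors, without the low-count filter and at 0.1, and 0 with the non-robust fit. The counts were 24 and 1 with DESeq2 and 73 and 28 in a fit of the groups alone.

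The 7 genes called with opposite signs became 1 with upper-quartile factors, without composition factors, with the strict filter and with the legacy method, 11 without the low-count filter, 1459 with DESeq2 and 1104 at 0.1. The 1 gene called in both tumour groups against sham became 2 with upper-quartile factors, without composition factors, without the filter and at 0.1, 24 with DESeq2 and 0 with the non-robust fit. The correlation of scrambled and knockdown changes from sham, 0.58, was 0.47 without the filter and 0.45 with limma-voom. That of scrambled against sham with knockdown against scrambled, -0.80, was -0.74 without the filter, -0.85 with the strict filter and -0.87 with limma-voom. With an estimated correlation 0, 0 and 1 gene lists passed, in the order of the comparisons, against 14, 12 and 14. In the same order fry called 10, 3 and 1. For other cell types 0, 0 and 0 passed with an estimated correlation and 0, 0 and 1 with fry, against 3, 2 and 7.

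No pairing by replicate number was seen. Deviations from the group mean correlated across genes at -0.06 to 0.17 between libraries of the same number, and 3 of 8 libraries correlated best with their own number. This check cannot exclude a pairing, since the deviations of the 2 sham libraries mirror each other by construction. With a replicate block the counts were 14 higher and 2 lower for scrambled against sham, and 0 and 0 for each of the other comparisons (4165 and 341 genes at an unadjusted p under 0.05), with 0 called in opposite directions and 0 in both tumour groups. The block leaves fewer degrees of freedom.

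Leaving out each library in turn, which leaves 1 sham library assumed to vary like the other groups in 2 of the 8 fits, the counts ran from 0 to 3441 higher and 0 to 3467 lower for scrambled against sham, 0 to 3705 and 0 to 3608 for knockdown against scrambled, and 0 to 23 and 0 to 9 for knockdown against sham. The highest of each came without scrambled library 2, where all 215 genes called between scrambled and sham were among the 6908. Genes called in opposite directions ran from 0 to 6218 and in both tumour groups from 0 to 26. The correlations ran from 0.46 to 0.63 and from -0.89 to -0.74. Gene lists called ran from 11 to 15, 12 to 14 and 11 to 16, and cell type lists from 2 to 5, 0 to 4 and 5 to 8. The mean log2 CPM of the neutrophil list, knockdown minus sham, ran from -0.23 (adjusted p = 0.943, limma camera), without sham library 2, to 1.41.

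Of 1380 comparisons of a called named gene with an alternative, 758 kept direction and call, 622 lost the call and 0 changed direction. By comparison, 695 of 1220 kept both for scrambled against sham, 52 of 140 for knockdown against scrambled, where 88 lost the call, and 11 of 20 for knockdown against sham. For called lists 496 of 624 kept both, 127 lost the call and 1 changed direction. On simulated data of this depth and number of libraries, 18% to 30% of genes changed by 2 fold were called, so changes of that size can be missed. The simulated data gave each gene 1 dispersion in every group, so the recovery of larger changes may be lower in the real fit. Between knockdown and sham, Cxcl13 and Serpina3n had large changes and were not called.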

Other observations

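In this part the tests on sterol synthesis and on the clock were chosen only after the results were seen. Some genes of cholesterol synthesis fell between sham and scrambled libraries: Sqle, Hmgcs1, Mvd (log2 -2.29 ± 0.44), an enzyme of the mevalonate pathway, and Srebf2 (-1.68 ± 0.24), the transcription factor that drives the pathway, were called by edgeR. A list of the pathway, written after these 4 were seen, had 26 tested members, 4 of them called and 24 with a negative log2 change, with a median log2 change of -1.94 against sham, and of 1.30 from scrambled to knockdown. Of its 22 members that were not called, 18, or 81.8%, were lower in every scrambled library than in both sham libraries, against 20.7% of all 13431 genes that were not called. Camera gave those 22 members p = 9.9e-09 with its preset correlation and p = 0.137 with an estimated one, so a fall of the pathway as a set stays open. Among them Idi1 (-2.95) and Cyp51 (-2.28) had an adjusted p of 0.0542 and 0.057 by edgeR. The sham libraries themselves differed, with list means of 4.39 and 5.45 log2 CPM against 3.06, 3.42 and 2.94 in the scrambled and 4.11, 5.06 and 4.08 in the knockdown libraries.

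Clock output genes had lower values in knockdown than in sham libraries, none of them called over all genes. The mean of Dbp, Nr1d1, Nr1d2, Per3, Tef and Hlf lay at -1.29, -0.86 and -1.24 log2 CPM from the sham mean in knockdown libraries 1, 2 and 3. A graded tumour effect as the only cause is argued against by the scrambled libraries, which lay on both sides of sham: -1.06 in library 2, but 0.50 and 0.70 in libraries 1 and 3, with 0.23 between the sham libraries. Collection at another time of day stays open: the mean of Arntl, Npas2 and Clock, of the opposite arm, lay 0.0814 log2 CPM higher in the lowest knockdown library than in the highest sham library, less than the 0.38 between the sham libraries. From the sham mean this arm lay at -0.47, 0.09 and -0.59 in scrambled libraries 1, 2 and 3, and at 0.35, 0.27 and 0.45 in knockdown libraries 1, 2 and 3. In each tumour library its sign was opposite to that of the output genes. In scrambled library 2, however, its mean (5.87 log2 CPM) lay between the sham libraries (5.59 and 5.97). In scrambled libraries 1 and 3 Arntl and Npas2 lay below both sham libraries. Clock lay above both in scrambled library 1 and between them in scrambled library 3. An unknown collection time may bear on the comparisons with the scrambled libraries too. An effect of the tumour on the clock itself stays open too, since the labels give no collection times.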
